A study of Arabidopsis thaliana with 10 samples.

How the data were processed

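The series holds 9 strand-specific sequencing libraries of the RNA of 12-day-old Col-0 Arabidopsis seedlings that is left after polyadenylated RNA and ribosomal RNA have been taken out, here called poly(A)- RNA. There is 1 library for each condition: an untreated control taken at 3 h, and cold (4 °C), heat (37 °C), salt (200 mM NaCl) and drought (300 mM mannitol, an osmotic stand-in for water shortage), each taken at 3 h and at 12 h. Reads were single-end and 100 nt long. 1 further sample, total RNA of mixed tissues with plants of 5 weeks, is not analysed here.

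The expression values of the libraries are RPKM (reads scaled to transcript length and to the mapped reads of the library) computed by the authors, per the file headers. The genome build was TAIR10, and Bowtie 0.12.9, TopHat2 2.0.8 and Cufflinks are named, per the submitters' processing notes; which of them made the RPKM, and by which counting rule, is not given in the sources used here. The other deposited values belong to transcripts and not to samples. DNA conservation is a deposited blastn bit score, structure conservation a deposited score (the structure conservation index, SCI), RNA stability a randfold p-value made by the authors, and histone marks and DNA methylation deposited scores of intensity whose unit and source plants are not given in the sources used here. The authors' deposited lists of stress-responsive lncRNAs rest on DEGseq with a p-value of at most 0.05 and a fold of at least 2, per the file headers. The deposited table of gene ontology (GO) terms gives p-values and false discovery rates by the authors; the tool is not given in the sources used here. Genomic class, polyadenylation class, structure class and level are the authors' classes, used as deposited. The tables also hold 20 columns of per-sample values, mainly of an earlier study of polyadenylated RNA, that were not used; of the stress columns in the list of predicted lncRNAs, only the order of the times in each pair was read.

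The reads behind each RPKM were recovered first. Within a library, RPKM times exon length falls on whole multiples of 1 step, which gives the number of mapped reads of the library and the whole reads of each lncRNA. For predicted lncRNAs all 2790 non-zero values came out whole, within 0.02 reads. For annotated lncRNAs only 79 of the 1922 non-zero values (4.11%) were whole at the exon length of their own row, against a mean of 4.06% and a highest of 7.02% over 1000 random orders. With the values given to the loci in the order of the number after the G of the locus identifier, 1922 of 1922 were whole, while ordering by start left 12.7% whole, by start as text 5.05% and by end 12.7%. All 384 annotated loci moved, and every annotated value below is the re-matched one. This choice was made after seeing the data, and for 39 annotated loci at 0 in every library it rests on the order alone. Isoforms of a locus share 1 value, so the 469 annotated and 995 predicted transcripts were counted as 384 and 978 loci, 1362 in all; 4396 further predicted loci, called level 3, carry no expression values.

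Each stress library was compared with the control library on log2(RPKM + 1). A lncRNA is called higher or lower where it differed by at least 2-fold on that scale, which understates the change of low lncRNAs. No condition has a replicate, so none was tested against the control; a test of time over the 4 stresses was not run. Ratios of RPKM are given with exact binomial 95% intervals of the reads, and shares with exact (Clopper-Pearson) 95% intervals; both cover counting error only. A fold against 0 reads is a lower bound against a floor of 3 reads per library, and none is given where both libraries lie at or under the floor. A common shift of a library was measured as its median ratio to the control over the 59 lncRNAs with at least 5 reads in every library.

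The 2-fold rule with a pseudocount of 1 RPKM is not even-handed, since a lncRNA under 1 RPKM in the control cannot be called lower. When 100 lncRNAs were simulated 4-fold higher and 100 4-fold lower than the control, in the comparison with drought at 12 h, the rule called 13.6 of the first and 4.13 of the second on average over 100 draws, which is 76.7% higher; at 8-fold it called 31.0 and 5.93 (83.9% higher). Over the 8 comparisons, with no difference in truth, it called a mean of 1.40 to 3.75 lncRNAs over 1000 simulations of the counting error.

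The steps were tested on simulated data over the 1362 lncRNAs. Read recovery returned 100% of the simulated reads. In a comparison simulated for drought at 12 h, the rule called 14% of the lncRNAs set 4-fold higher, 4% of those set 4-fold lower, 40% of those set 8-fold higher and 8% of those set 8-fold lower, and 4 of 1162 unchanged ones. The permutation test, run on 1464 transcripts, gave a p-value under 0.05 in 6% of simulated pairs with no difference.

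Shares of one sign at both times and overlaps between stresses all use the same control library, so they were also computed for simulated unchanged libraries against that control. Overlaps are set beside the overlap of independent lists, and their odds ratios only describe the lists. Independent lists were drawn from all lncRNAs and, chosen after seeing the data, from a narrower background. For lower lncRNAs this is those that the rule can call lower, and for higher ones those with any reads. The latter still holds lncRNAs that cannot be called higher, since such a call needs at least 1 RPKM in the stress library. Features of transcripts were compared by two-sided permutation tests of the difference of medians with 100000 resamples, and classes and GO themes by two-sided Fisher's exact tests, each with Benjamini-Hochberg adjustment within its family. These tests are across transcripts or lncRNAs, which are not independent replicates of the study.

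The lncRNAs named were set by a rule: for each stress the 3 with the largest increase and the 3 with the largest decrease at either time among those with at least 1 RPKM in 1 of the pair; up to 10 that were higher, and up to 10 that were lower, under all 4 stresses; the 5 longest predicted lncRNAs of level 1; a fixed list of known noncoding RNAs; and the 10 GO terms with most lncRNAs with the 3 smallest p-values of each theme. The rule also asked for the highest-scoring predicted lncRNAs, but no such score was used here, so that part was not applied. The deposited lists give no folds, so folds come from the RPKM. The lncRNAs with the most reads, the lncRNAs of the authors' list with most reads and those that host small RNAs were chosen after their values were seen. The designs, the named-gene rule and the first set of alternatives were fixed before the data were examined; the rescaling of libraries, the rule without a pseudocount, the limit of 1 RPKM on the mean, the separate counts of annotated and predicted lncRNAs, the exchange of the cold columns and the other reference libraries were chosen after seeing the data.

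Coordinates are those of the authors' files (TAIR10). Gene names and neighbours come from the RefSeq annotation of the TAIR10.1 assembly, in which all 384 annotated loci overlap the locus of the same identifier, with the same start in 56.8% and the same end in 57.6%. Copies of a lncRNA were counted with BLAST+ 2.17.0 as matches of at least 95% identity over at least 80% of its length; 67 predicted and 5 annotated lncRNAs had more than 1. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.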

Results

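The study asked which long noncoding RNAs (lncRNAs) of Arabidopsis seedlings respond to abiotic stress, in the RNA fraction without poly(A) tails. The catalogue measured holds 384 annotated loci and 978 predicted ones, of which 358 are level 1 and 620 level 2. The control library held 25.2 M mapped reads, those of cold at 3 h and 12 h 32.9 M and 31.8 M, of heat 37.0 M and 34.4 M, of salt 31.5 M and 17.6 M, and of drought 26.1 M and 21.0 M. Reads on lncRNAs ran from 10399 in salt at 12 h to 22293 in cold at 12 h, and 1 annotated lncRNA, AT1G15405, took from 24.5% to 45.7% of them. At least 1 read fell on 284 lncRNAs in the control, and on 458 (heat at 3 h) to 656 (drought at 12 h) in the stress libraries. In the stress libraries the median of the 59 lncRNAs read in every library was shifted against the control by log2 0.41 and 0.59 in cold at 3 h and 12 h, 0.04 and 0.39 in heat, 0.14 and 0.75 in salt, and 0.46 and 0.91 in drought. Folds below are not corrected for this shift; the 2-fold split of each stress library is given with and without it.

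**Figure D1:**
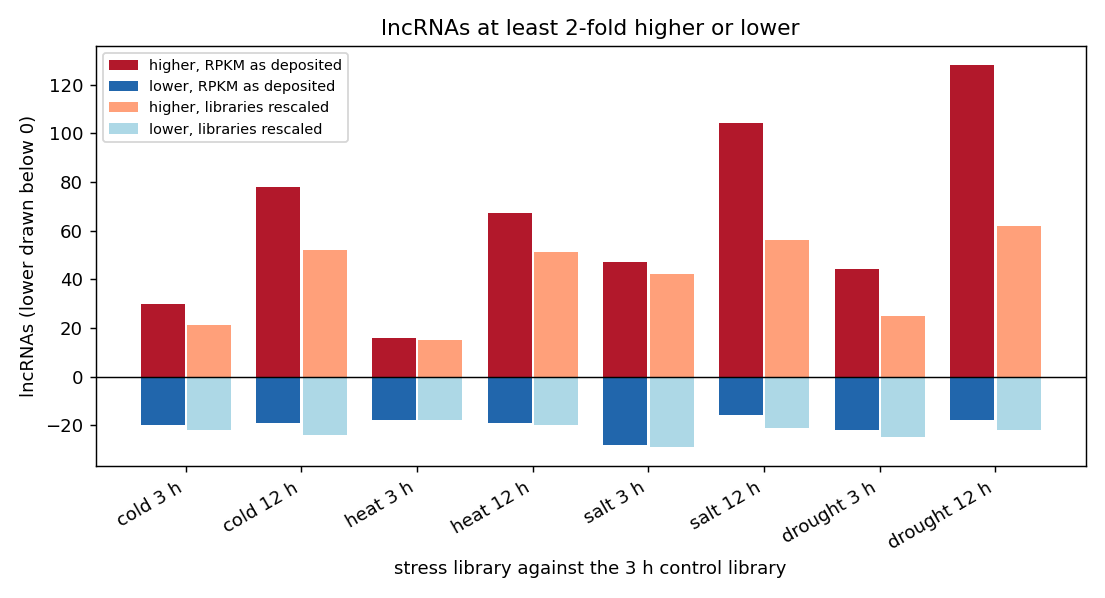
Number of lncRNAs called higher or lower by at least 2-fold on log2(RPKM + 1) against the control library, for each of the 8 stress libraries (1 library each), with RPKM as deposited and after rescaling each library; bars of lower lncRNAs are drawn below 0. With RPKM as deposited, heat at 3 h (16 higher, 18 lower) is the only comparison with more lower than higher lncRNAs under this rule.

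Cold. The largest increase at 3 h was at level1_lnc-339 (chromosome 5, 23384412 to 23384706, plus strand), which lies within the coding gene AT5G57710 on the same strand, so that reads of that gene's own RNA were not separated from it. It had 12 reads in the control and 234 in cold at 3 h, 14.9-fold higher (8.38 to 29.3), and was 4.35-fold higher (2.33 to 8.85) at 12 h. At 12 h level2_lnc-43 (chromosome 1, 8908908 to 8909243, minus strand), within the protein kinase gene AT1G25390 on the same strand, went from 0 to 58 reads, at least 15.3-fold higher. The intergenic level1_lnc-278 (chromosome 5, 7891222 to 7891663, minus strand), 867 bp from HMGB6, a gene of the high-mobility group box family, went from 2 to 116 reads, a ratio of 45.9 (12.4 to 384). Among the lower ones, level2_lnc-18 (chromosome 1, 4662844 to 4663495, minus strand), opposite the defensin-like gene AT1G13609, was 11.6-fold lower (7.22 to 19.8) at 3 h but 2.24-fold higher (1.87 to 2.68) at 12 h.

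Of the 1362 lncRNAs, 30 were higher and 20 lower in cold at 3 h (60% higher, 45.2 to 73.6), and 78 were higher and 19 lower at 12 h (80.4%, 71.1 to 87.8). After rescaling the splits were 21 to 22 (48.8%) and 52 to 24 (68.4%), and at 4-fold 3 were higher and 7 lower at 3 h against 19 and 7 at 12 h. Annotated lncRNAs alone gave 7 higher and 9 lower at 3 h, and 16 and 10 at 12 h (rescaled 5 to 9 and 10 to 13). The authors' list gives cold pairs in the reverse order of their full matrix, so which cold column is 3 h rests on the column names of the matrix.

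Heat. The largest increase was at level2_lnc-245 (chromosome 2, 15025720 to 15025965, plus strand), opposite INT3, an inositol transporter gene. The lncRNA gene AT2G35738 overlaps it on its own strand. Level2_lnc-245 had 0 reads in the control, 1 in heat at 3 h and 231 at 12 h, at least 56.5-fold higher. Next came level2_lnc-185 (chromosome 2, 3607063 to 3607302, plus strand), classed as a small RNA precursor, with 1 control read and 108 in heat at 12 h, a ratio of 79.2 (13.9 to 3156). Its sequence has 30 copies in the genome, itself included, and whether its reads also map to the others was not tested. The antisense level2_lnc-385 (chromosome 3, 22283586 to 22283966, minus strand), which also overlaps the coding gene AT3G60286 on its own strand, so that reads of that gene were not separated, had 25 reads at 12 h and 0 in the control, at least 6.11-fold higher, on exons of 97 nt, shorter than a read. At 3 h level2_lnc-18 fell from 169 reads to 2, 124-fold lower (33.9 to 1035), and at 12 h it had 219 reads, 1.05-fold lower (0.856 to 1.29).

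In heat at 3 h 16 lncRNAs were higher and 18 lower (47.1% higher, 29.8 to 64.9), and at 12 h 67 were higher and 19 lower (77.9%, 67.7 to 86.1). Rescaled, these were 15 to 18 (45.5%) and 51 to 20 (71.8%). Annotated lncRNAs alone gave 2 higher and 8 lower at 3 h, and 8 and 10 at 12 h (rescaled 2 to 8 and 7 to 11). At 4-fold 1 was higher and 9 lower at 3 h, and 14 were higher and 9 lower at 12 h. The split at 3 h turns with the pseudocount: without one, where the counting interval excludes 1, 50 were higher and 24 lower (67.6%, 55.7 to 78.0), and with 0.1 RPKM 176 and 79 (69.0%).

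Salt. The largest increase was at level2_lnc-376 (chromosome 3, 20872805 to 20873677, plus strand), a small RNA precursor by class that overlaps the transcribed pseudogene AT3G56275. It had 0 reads in the control, 75 in salt at 3 h (at least 20.0-fold higher) and 103 at 12 h (at least 49.2-fold higher), and in drought 47 and 72 reads. In salt at 12 h level1_lnc-249 (chromosome 5, 1640962 to 1641178, plus strand), within EMB2771 and on its strand, went from 2 to 36 reads, a ratio of 25.8 (6.64 to 221). Lower was AT3G22121 (chromosome 3, 7795606 to 7796327, plus strand), opposite CWLP, which codes for a cell wall-plasma membrane linker protein: 273 reads in the control, 14 at 3 h (24.4-fold lower, 14.3 to 45.2) and 10 at 12 h (19.1-fold lower, 10.2 to 40.2). It was lower in the other stresses too, from 45 reads in cold at 3 h to 7 in heat at 3 h (57.4-fold lower, 27.5 to 144). Among lncRNAs with most reads, AT1G05562 (chromosome 1, 1645875 to 1647162, plus strand), opposite the glucosyltransferase gene UGT75B1, had 189 reads in the control and 979 in salt at 3 h, 4.14-fold higher (3.54 to 4.86).

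In salt at 3 h 47 lncRNAs were higher and 28 lower (62.7% higher, 50.7 to 73.6), and at 12 h 104 and 16 (86.7%, 79.3 to 92.2). Rescaled, the splits were 42 to 29 (59.2%) and 56 to 21 (72.7%). Annotated lncRNAs alone gave 8 higher and 14 lower at 3 h, and 18 and 7 at 12 h (rescaled 7 to 15 and 7 to 10). At 4-fold 5 were higher and 7 lower at 3 h, and 27 and 7 at 12 h; the 12 h library was the smallest of the series.

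Drought. The largest increase was at AT3G12965 (chromosome 3, 4136961 to 4137674, minus strand), 133 bp from SMP1, a seed maturation protein gene on the other strand. It had 3 reads in the control, 20 in drought at 3 h, a ratio of 6.43 (1.91 to 33.8), and 108 at 12 h, a ratio of 43.1 (14.4 to 212); in cold at 12 h it had 80. Level1_lnc-322 (chromosome 5, 19772865 to 19773206, plus strand) lies opposite the disease resistance gene AT5G48770 and overlaps the lncRNA gene AT5G48775 on its own strand. It had 0 control reads, 19 at 3 h and 52 at 12 h, at least 20.8-fold higher. The level1_lnc-341 transcript, within CRCK1 and on its strand, had 25 reads in drought at 3 h and 0 at 12 h, on exons of 97 nt. The largest decrease was at level1_lnc-169 (chromosome 3, 12670276 to 12670499, plus strand), which overlaps the transcribed pseudogene AT3G31161 and has 21 copies: 485 reads in the control, 1 in drought at 3 h (a ratio of 503 in favour of the control, 89.8 to 19891) and 0 at 12 h (at least 135-fold lower). It was also the largest decrease in cold, heat and salt. At 3 h and 12 h it had 0 and 0 reads in cold, 0 and 76 in heat, and 17 and 0 in salt.

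In drought at 3 h 44 lncRNAs were higher and 22 lower (66.7% higher, 54.0 to 77.8), and at 12 h 128 and 18 (87.7%, 81.2 to 92.5), the most of any comparison. Rescaled, the splits were 25 to 25 (50%) and 62 to 22 (73.8%), and at 4-fold 5 were higher and 6 lower at 3 h against 30 and 5 at 12 h. Annotated lncRNAs alone gave 16 higher and 9 lower at 3 h, and 26 and 8 at 12 h (rescaled 8 to 10 and 9 to 9). In all 8 comparisons the rule itself calls increases more readily than decreases.

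**Figure D2:**
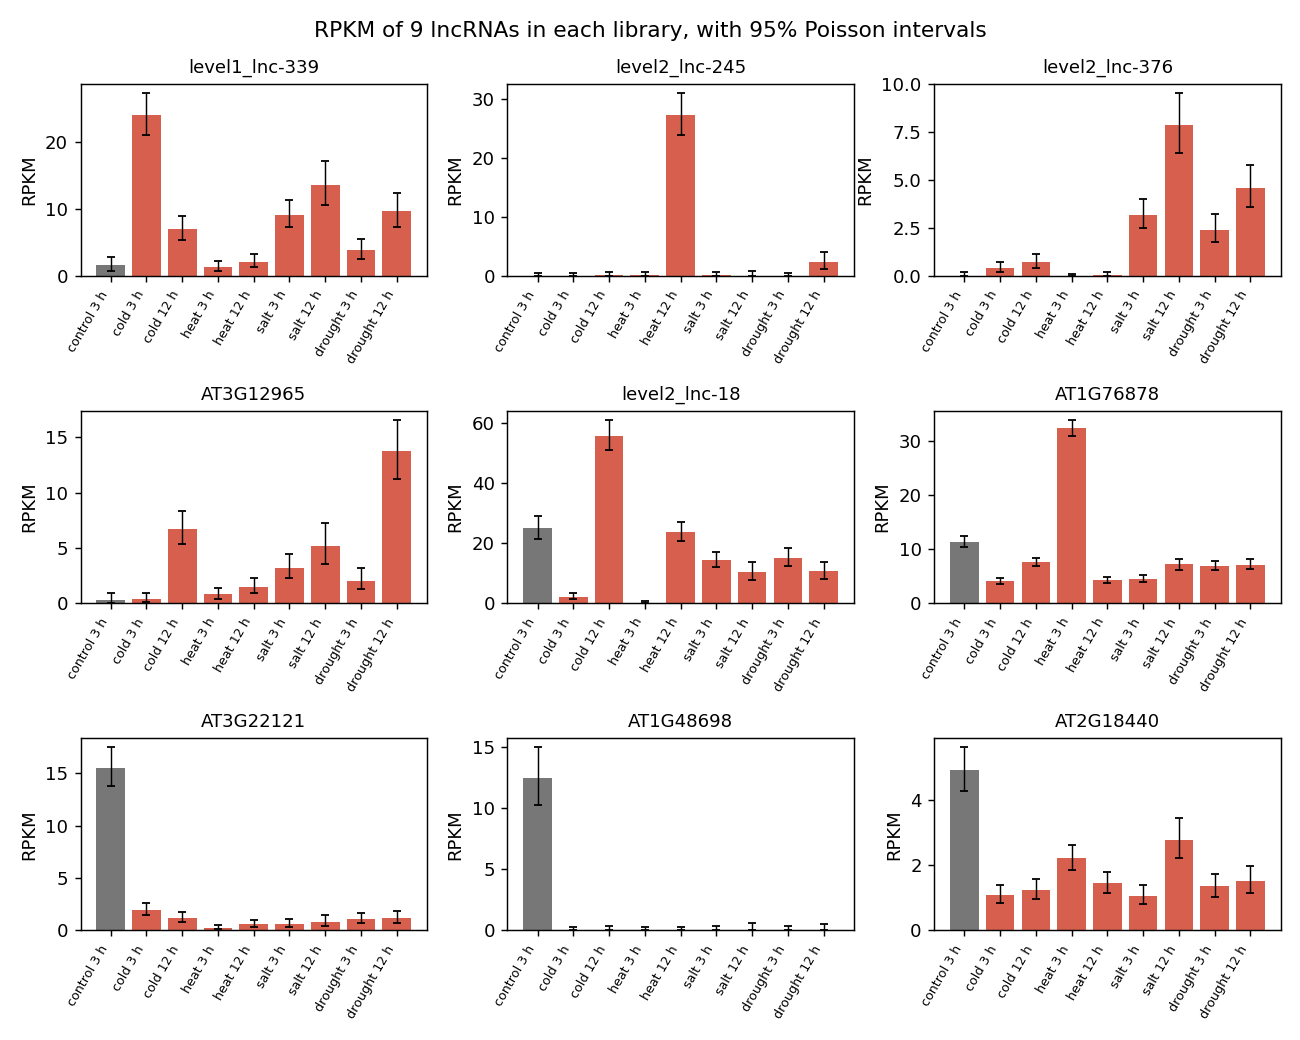
RPKM of 9 lncRNAs in the control (grey bar) and in the 8 stress libraries (red bars), 1 library each, with exact Poisson 95% intervals. AT3G22121, AT1G48698 and GUT15 (AT2G18440) stand highest in the control, at 15.5, 12.4 and 4.92 RPKM, and level2_lnc-245 in heat at 12 h, at 27.3 RPKM.

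The study sampled each stress at 3 h and 12 h. Of the lncRNAs whose RPKM differed from the control at both times, the sign against the control was the same in 378 of 452 in cold (83.6%, 79.9 to 86.9), 367 of 440 in heat (83.4%, 79.6 to 86.8), 388 of 460 in salt (84.3%, 80.7 to 87.5) and 376 of 465 in drought (80.9%, 77.0 to 84.3). These include lncRNAs with reads in the control and 0 at both times, which count as the same sign. Simulated unchanged libraries, with a simulated control in common, gave 73.3%, 73.9%, 69.1% and 68.7%. The covariance of the log2 folds was 0.142, 0.116, 0.168 and 0.165, against 0.0203, 0.0204, 0.0204 and 0.0203 simulated. The correlation was 0.611, 0.563, 0.644 and 0.600, against 0.558, 0.581, 0.481 and 0.481 simulated, and so not above the simulated value in heat. The simulated libraries hold counting error only and vary far less than the data, so the 2 sets of correlations are not on like terms. Any variation of the control library beyond counting error is missing from the simulation, so neither measure decides what the shared control gives. Of lncRNAs changed 2-fold at both times, 28 of 29 in cold, 22 of 23 in heat, 45 of 45 in salt and 38 of 39 in drought had the same direction; in simulated unchanged libraries 100% of the few that pass had, so these shares do not set the stresses apart from the shared control.

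Several lncRNAs differed from the control the same way under every stress, at 3 h or 12 h of each. Lower under all 4 were 17, among them AT1G48698, with 111 reads in the control and 0 in all 8 stress libraries, at least 25.8-fold to at least 54.4-fold lower. Also among the 17 were level1_lnc-169 and AT3G22121, described under drought and salt, with 485 and 273 reads in the control. AT3G27990 had 143 reads in the control and at most 4 in any stress library, AT2G33815, opposite SPL3, a transcription factor gene that promotes flowering, 129 reads against 1 to 24, and AT1G54355, opposite ABCD2, 127 reads against 8 to 36. AT1G31935, AT4G37553, level1_lnc-24 and level2_lnc-190 were also lower under all 4, though level2_lnc-190, on the strand of the coding gene AT2G11225, had 13 reads in heat at 12 h against 12 in the control. Higher under all 4 were 14, or 14 at 12 h alone and 2 at 3 h alone, against 17, 12 and 11 lower ones, so the higher ones rest on the 12 h libraries, which have no control of their own time. Among the 14 were level1_lnc-249 within EMB2771, level1_lnc-53 within AT1G51570, level2_lnc-479 within the autophagy-like gene AT4G30790, level1_lnc-315 opposite UMAMIT1, level1_lnc-322, and the small RNA precursors level1_lnc-170, level2_lnc-185, level2_lnc-187, level2_lnc-413 and level2_lnc-560, which have 8, 30, 63, 74 and 77 copies. The 3 within coding genes lie on their strand, so reads of those genes were not separated. Alone of those named, level2_lnc-560 was under 2-fold in some stresses after rescaling, with log2 at most 0.861 in cold, 0.801 in salt and 0.934 in drought. Level1_lnc-170 had 75 reads in the control and 554 in cold at 12 h, 5.85-fold higher (4.59 to 7.54), and 507 in drought at 12 h, 8.10-fold higher (6.35 to 10.5).

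Pairs of stresses shared 21 to 53 higher lncRNAs, where independent lists drawn from the 1114 with any reads would share 6.46 to 16.2 (5.29 to 13.2 from all 1362). A call of higher needs at least 1 RPKM in the stress library, which many of the 1114 never reach. Of predicted loci, 31 of the transposable element class and 248 others reached it in any library, and of annotated loci 7 and 71. Both independent overlaps are therefore too low, and an excess of shared higher lncRNAs is not shown. Pairs of stresses shared 18 to 23 lower lncRNAs. Independent lists from the 55 that the rule can call lower, those with at least 1 RPKM in the control, would share 9.62 to 13.2. The 0.388 to 0.532 from all 1362 counts lncRNAs that cannot be called. Simulated unchanged libraries with a simulated control in common shared 0.369 to 0.474 higher and 0.479 to 0.723 lower. By count salt and drought shared the most, 53 higher and 23 lower, and have the longest lists of higher lncRNAs. By odds ratio of the higher ones cold and salt stood above them (11.1 against 9.30), but below them after rescaling (13.3 against 21.2). The single control enters every list and cannot be split, so part of any excess may come from it. All the calls of lower lncRNAs rest on the reads of that 1 library.

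Of the fixed list of known noncoding RNAs, GUT15 (AT2G18440), first described for its unstable transcript, had 210 reads in the control and a lower RPKM in all 8 stress libraries: 4.50-fold lower in cold at 3 h (3.37 to 6.09), 4.61-fold in salt at 3 h (3.43 to 6.29) and 1.77-fold in salt at 12 h (1.36 to 2.31). DRIR (AT1G21529), a regulator of drought and salt responses, had 0 reads in the control, 10 in cold at 3 h (at least 2.55-fold higher) and at most 2 in the other libraries, drought and salt included. ASCO (AT1G67105), which binds splicing factors, had 1 read in the control, 9 at each time in cold and 12 in salt at 12 h, a ratio of 17.2 (2.54 to 735). ELENA1 (AT4G16355), an immune response lncRNA, had 0 to 2 reads throughout, so no difference was detectable at this depth. The other members of the list were not analysed here. None of the fixed cold, heat, osmotic and clock genes, such as CBF1, HSFA2, RAB18 and CCA1, had a lncRNA of the catalogue within 1000 bp.

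The 5 longest predicted lncRNAs of level 1 were low. Level1_lnc-156 (2530 nt) had 0 reads in the control and 17 in cold at 12 h, at least 4.49-fold higher, and level1_lnc-248 (1765 nt) had 0 and, in drought at 12 h, 21, at least 8.39-fold higher; both lie on pseudogenes. Level1_lnc-177 (975 nt) had 9 reads in the control and 42 in salt at 3 h, 3.73-fold higher (1.79 to 8.71). Level1_lnc-200 and level1_lnc-27 had at most 13 and 9 reads in any library.

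The authors' deposited table of responsive lncRNAs names 125 annotated transcripts, all classed Poly(A)+: 64 for high light, 58 for heat, 37 for salt, 25 for drought and 21 for cold. Among predicted ones it names 159 Poly(A)+ and 58 Poly(A)- transcripts. Of those 58, whose calls rest on the libraries analysed here, 28 are listed for drought, 17 for salt, 15 for heat and 13 for cold. The most reads in a library of a listed stress were at level2_lnc-102, listed for cold, drought and salt, with 1 read in the control, 44 in cold at 12 h and 18 in salt at 12 h. Level1_lnc-285 had 0 reads in the control and 23 in drought at 12 h. Of the 58, 54 had 0 control reads, and 38 had under 10 reads in each library of the stresses they are listed for. In any comparison, whether or not of a listed stress, 35 passed the 2-fold rule used here.

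Predicted lncRNAs were shorter than annotated ones, with lower median intensity of every histone mark but H3K9me2, and of H3 itself. The median exon length was 295 nt against 873 nt, the median exon number 1 against 2 and the median bit score of DNA conservation 136 against 161. H3K4me3, a mark of active promoters, had a median intensity of 0.669 against 4.74, H3K9Ac 1.54 against 5.64, H3K36me3, a mark of transcribed gene bodies, 0.447 against 2.98, H3K27me3, a Polycomb mark, 1.05 against 1.72, H3K27me1, a mark of heterochromatin, 0 against 5.21, and H3 itself 1.45 against 1.96, so the difference is not one of active marks alone. Each of these had p = 1e-05, the smallest the permutations can give, and adjusted p = 1.5e-05 across 995 and 469 transcripts. Of the 18 features 15 passed an adjusted p of 0.05. CpG methylation was lower in predicted ones, 8.93 against 12.9 (adjusted p = 0.0442 by permutation). At level 2 alone it was higher by 6.74 (adjusted p = 0.0298 by permutation), and at 200 nt or more the difference of -3.68 did not pass (adjusted p = 0.069 by permutation). CHH methylation did not pass (adjusted p = 0.548 by permutation), but at level 2 alone it was higher by 2.36 (adjusted p = 0.0116 by permutation). For structure conservation and H3K9me2 both medians are 0, so a test of medians could not find a difference. Their upper quartiles were lower in predicted ones, 0 against 0.53 for structure conservation and 3.88 against 6.51 for H3K9me2, which was not tested.

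Changed predicted transcripts were shorter than unchanged ones and had more of the active marks. The median length was 254 nt in 281 changed and 310 nt in 714 unchanged (adjusted p = 4.5e-05 by permutation), H3K4me2 was 2.09 against 1.13 (adjusted p = 4.5e-05), H3K4me3 1.14 against 0.669 (adjusted p = 4.5e-05) and H3K9Ac 2.16 against 1.41 (adjusted p = 4.5e-05). H3K36me2, H3K36me3 and H3K18Ac also passed, 7 of 18 features in all by permutation test across transcripts; among transcripts with reads 5 did, and H3K36me3 (adjusted p = 0.0635) and H3K18Ac (adjusted p = 0.166) did not. 1 read on a short transcript is worth more RPKM, so the rule itself favours short ones. The rule also called nearly every predicted locus with at least 1 RPKM in any library. These were 30 of 31 transposable element loci and 239 of 248 others. Marks were not compared at matched expression, so the difference in active marks cannot be told apart from one of expression level. Among annotated lncRNAs 0 of 18 features passed, across 64 changed and 405 unchanged transcripts. The marks named above were still higher in changed ones, by 2.72 for H3K4me3, 1.91 for H3K9Ac, 1.28 for H3K36me3, 0.743 for H3K36me2, 0.504 for H3K4me2 and 0.215 for H3K18Ac. Length went the other way, by 32 nt. With the authors' list in place of the 2-fold rule 1 feature passed, the bit score of DNA conservation (a difference of -18, adjusted p = 0.00036 by permutation), which is not among the 7.

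By genomic class, antisense lncRNAs made up 25.7% of predicted (256 of 995, 23.0 to 28.6) and 40.9% of annotated transcripts (192 of 469, 36.5 to 45.5; adjusted p = 4.06e-08, Fisher's exact test). Intergenic ones made up 23.5% and 12.6% (adjusted p = 1.79e-06, Fisher's exact test). The shares of transposable element, cis, pseudogene and small RNA precursor lncRNAs did not pass. Changed in any comparison were 57 of the 384 annotated loci (14.8%) and 269 of the 978 predicted ones (27.5%). Within predicted loci, cis lncRNAs were changed in 31.5% (78 of 248), intergenic in 29.6% (67 of 226) and transposable element ones in 21.7% (30 of 138); no class of predicted or annotated lncRNAs passed against the others, the smallest adjusted p being 0.367.

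The authors' deposited table joins 185 lncRNAs, 40 annotated and 145 predicted, to 338 GO terms of coding genes expressed together with them. The terms with most lncRNAs were cell and cell part, with 177 each, and intracellular, with 135. The deposited p-values are for enrichment of a term among the co-expressed coding genes, and not for its number of lncRNAs. Among stress terms, response to abiotic stimulus had 55 lncRNAs (p = 1.4e-36 as deposited by the authors), response to temperature stimulus 34 (1.2e-30) and response to cold 28 (5.6e-20). Response to auxin stimulus had 31 (1e-15), defense response 46 (4.6e-31), transcription 77 (1.6e-37) and plastid thylakoid 27 (3.4e-33). By theme, transport joined 82 lncRNAs, chromatin and transcription 80, photosynthesis and plastid 78, abiotic stress 60, reproduction and flower 58, hormone 57, defence 48, cell wall 42, translation and ribosome 37, root and leaf development 23 and RNA processing 17. Of changed lncRNAs 25 of 52 (48.1%) had an abiotic stress term, and of unchanged ones 35 of 133 (26.3%), an odds ratio of 2.59 (p = 0.00548, adjusted p = 0.0657, Fisher's exact test across lncRNAs), which did not pass after adjustment; neither did any other theme.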

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

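The depth test, the test of a common shift at 12 h alone and all tests of the order of values and of the cold columns were chosen only after the result was seen.

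A pair of time points under 1 stress went opposite ways by at least 2-fold for 3 lncRNAs, and these differences were not tested. Level2_lnc-18, opposite the defensin-like gene AT1G13609, was at log2 -3.04 in cold at 3 h and 1.13 at 12 h (169 reads in the control, then 19 and 478), and 0.56 at 12 h after rescaling. AT1G76878, opposite the homeodomain-like gene AT1G76880, was at 1.43 in heat at 3 h and -1.21 at 12 h (451, 1885 and 235 reads). AT2G23672 (chromosome 2, 10063245 to 10064004, plus strand), of the transposable element class, was at -1.08 in drought at 3 h and 1.096 at 12 h (306, 139 and 564 reads), and 0.22 at 12 h after rescaling.

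By the 2-fold rule, in every comparison but heat at 3 h more lncRNAs were higher than lower than the control; among annotated ones alone this held in cold and salt at 12 h and drought at both times, but not in cold, heat and salt at 3 h and heat at 12 h, and after rescaling in none. Depth is argued against as the source of the greater number of detected lncRNAs. With all libraries thinned to the smallest, the median stress library still had 1.90 times (1.81 to 2.02 over draws) the detected lncRNAs of the control. The split of higher and lower lncRNAs was not recomputed at equal depth. The test therefore cannot decide whether depth adds to the split. A common shift stays open. Over all 8 comparisons the median after rescaling was 63.8% higher (54.0 to 72.6 over resampled lncRNAs), an interval that did not clear the bound set against a shift. At 12 h alone the median was 72.3% (68.4 to 73.8, the range over the 4 comparisons), and the interval of each comparison met the bound of 50% set against a shift. That bound was wrong, because balanced simulated changes give 76.7% to 85.2% higher under this rule. Time since the control cannot be told apart from stress (a median of 61.3% higher at 3 h, with a range of 47.1 to 66.7 over the stresses), as there is no control at 12 h and the stresses themselves are untested with 1 library each. The readiness of the 2-fold rule to call increases also stays open. Among 95 lncRNAs with a mean of at least 1 RPKM the median share was 71.4% (61.6 to 83.9 over resampled lncRNAs), which met the bound set beforehand against it. That bound was wrong, because 53 of the 95 lie under 1 RPKM in the control, where no decrease can be called.

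Reads per annotated lncRNA were not whole at the exon length of their own row. Exon lengths of another annotation are argued against, with 4.16% of values whole at the reference lengths. Values listed in the order of the number in the identifier may be the source: 100% were whole after that re-match, and under random orders at most 7.02% were. No biological explanation was tested. The authors' polyadenylation classes run against the re-match, for a reason not tested: the median highest RPKM was 0.397 as deposited and 0.145 re-matched in Bimorphic, 0.163 and 0.102 in Poly(A)- (0 and 3 of 11 loci without reads) and 0.241 and 0.329 in Poly(A)+.

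All 33 cold pairs that differ in the authors' list of responsive lncRNAs stand in the order 12 h, 3 h of the full matrix, while 33 heat, 38 salt and 41 drought pairs stand in the order 3 h, 12 h. An exchange of the cold columns in the matrix could give this, as could an exchange in the list. Of 6 lncRNAs at least 2-fold higher at 12 h in heat, salt and drought, 4 were higher in the column named cold 12 h (66.7%, 22.3 to 95.7), and with at least 2 of these stresses asked for, 16 of the 24 that differ in cold were (44.7 to 84.4). Detected lncRNAs (479 and 635) and the share higher than the control (60% and 80.4%) rise from the column named cold 3 h to that named 12 h, as from 3 h to 12 h in the other stresses, but both intervals include 50% and no bound was set on such rises, so the exchange cannot be told apart from the order as named. No biological explanation was tested.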

How the results depend on the processing

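The rescaling, the rule without a pseudocount, the limit of 1 RPKM on the mean, the annotated-only and predicted-only counts and the exchanged cold columns were chosen only after seeing the data. So were the narrower backgrounds of the overlaps, the rows as deposited and the authors' list in place of the 2-fold rule. The following counts are of pairs of a result and an alternative, so 1 result enters once per alternative. Of the pairs of main results 77 kept their direction and size or side of the threshold, 72 moved and 2 reversed. Of the 77, 8 belong to the limit at the median of listed values, which could change nothing. Of the pairs of single lncRNAs, features, classes and themes 157 kept, 59 moved, 39 reversed, 15 lost and 2 gained their threshold. Where not said otherwise the cause was not tested. Counts of changed lncRNAs are given for cold at 3 h and 12 h, then heat, salt and drought likewise. At 4-fold they were 10, 26, 10, 23, 12, 34, 11 and 35, with 30%, 10%, 41.7% and 45.5% higher at 3 h in cold, heat, salt and drought and 60.9% in heat at 12 h; fewer pass by construction. With a pseudocount of 0.1 they were 309, 437, 255, 412, 363, 471, 344 and 524, since lncRNAs of few reads then pass, with 76.7% and 88.1% higher in cold, 69.0% in heat at 3 h, 77.7% in salt at 3 h and 79.4% in drought at 3 h. Without a pseudocount but with a counting interval that excludes 1, they were 84 and 161 in cold, 74 (67.6% higher) and 138 in heat and 106 in drought at 3 h. With a mean of at least 1 RPKM they were 29, 48, 18, 42, 48, 57, 42 and 58, from fewer lncRNAs. Annotated lncRNAs alone gave 16, 26, 10, 18, 22, 25, 25 and 34, and predicted alone 41 in drought at 3 h. Rescaled libraries gave 77 in salt and 84 in drought at 12 h, with 68.4% higher in cold, 72.7% in salt and 73.8% in drought at 12 h and 50% in drought at 3 h. Of the named lncRNAs AT3G55485 in drought at 12 h, which passed no threshold, went from log2 0.80 to -0.10 with rescaling, and AT1G15405 from 0.41 to -0.17 in cold and 0.15 to -0.24 in heat at 12 h, and from 0.34 to -0.12 and 0.33 to -0.58 in drought. Others that turned with rescaling, past no threshold, were AT1G05562 in drought at 12 h, AT3G55485 in cold at 12 h and drought at 3 h, AT3G12965, level2_lnc-479 and level1_lnc-170 in cold at 3 h, level1_lnc-177 in salt at 12 h and AT1G67105 in drought at 12 h. Exchanging the cold columns exchanges 50 and 97. Of lncRNAs changed at both times 96.6%, 95.7%, 100% and 97.4% kept their sign in cold, heat, salt and drought, as do 100% in simulated unchanged libraries, by the selection on size and the shared control. At 3 h only, 2 lncRNAs were higher and 11 lower under all stresses. The median ratio of shared to independent calls was 3.99 for higher lncRNAs, 9.17 at 3 h only, 6.39 rescaled and 0.955 within changed lncRNAs; for lower ones it was 45.0, 57.4 at 12 h only, 40.4 rescaled and 10.8 within changed lncRNAs. That last background is the union of the lists themselves, which lowers the ratio by construction. Within lncRNAs with any reads the ratio was 3.26 for higher ones, a background that still holds lncRNAs that cannot be called higher. Within lncRNAs that the rule can call lower the ratio was 1.82 for lower ones. Most of the ratio of 45.0 thus comes from lncRNAs that cannot be called lower. For features of changed lncRNAs, annotated ones gave 0 of 18 past the threshold and turned length (32 nt), bit score (9), H3K27me3 (0.0953) and CHH (0.0599). The active marks kept their direction there, among them H3K4me3 (2.72), H3K9Ac (1.91), H3K36me3 (1.28), H3K36me2 (0.743), H3K4me2 (0.504) and H3K18Ac (0.215). The authors' list gave 1, the bit score (-18), and turned H3K27me3 (0.0154), H3K36me3 (-0.0160), H3K4me2 (-0.225) and CHH (0.741). Between predicted and annotated, CHH turned to -1.54 at level 1 alone, and CpG to 6.74 and CHG to 0.369 at level 2 alone. Odds ratios of classes that passed no threshold turned on the rows as deposited (transposable element 1.05, antisense 0.926, cis 1.31, small RNA precursor 0.696), with at least 1 RPKM in any library (predicted transposable element 1.13, antisense 2.87, cis 0.408, small RNA precursor 0.428) and at 200 nt or more (small RNA precursor 1.04); that limit of 1 RPKM leaves no value for annotated pseudogenes and no finite one for intergenic lncRNAs. Odds ratios of GO themes turned in cold alone (defence 2.30, reproduction 1.72), heat alone (translation 0.782, cell wall 0.970, transport 0.781), salt alone (translation 0.807, transport 0.867, root and leaf 0.785), drought alone (defence 1.21, translation 0.952, transport 0.890, root and leaf 0.718) and with the authors' list (hormone 0.879, defence 1.04, translation 0.874, RNA processing 0.177, chromatin 0.762, cell wall 0.643, root and leaf 0.568), none past the threshold. Counting each theme once per lncRNA gave 582 pairs in place of 2109, by construction. The cell cycle theme holds 0 terms and has no value. The limit at the median of listed values was void, as that median is 0 and it removes 0 lncRNAs. No replicate numbers pair the libraries across groups; 12 h and 3 h of the same stress were compared as values, and a test of time over the 4 stresses was not run. Depth limits every call of a lncRNA with 0 to 3 reads in the control.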

Other observations

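The references other than the control and the small RNA hosts were chosen only after the result was seen.

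Several lncRNAs overlap genes of small RNAs on the same strand, 15 of the annotated and 4 of the predicted loci, and among the 10 annotated lncRNAs with most reads 4 do. Annotated hosts held 15.7% of the reads of annotated lncRNAs. AT2G46192, over 5 snoRNA genes (small nucleolar RNAs guide the modification of ribosomal RNA), had 17.1 RPKM in the control, 4.06 in salt at 3 h and 57.2 in drought at 3 h. Of the 13 snoRNA hosts 9 were lower and 4 higher in salt at 3 h, with and without rescaling, and 11 higher and 2 lower in heat at 12 h likewise; in drought at 12 h 11 were higher and 2 lower, but 8 and 5 after rescaling, and in salt at 12 h 10 and 3, but 5 and 8. The group was not tested. Lower in salt at 3 h were AT5G06165 with 5.31 RPKM in the control and 1.31 there, AT1G15002 with 4.56 and 1.09, and AT3G55485 with 38.8 and 30.8, 1.26-fold lower (1.11 to 1.43). Higher there were AT5G15022 with 1.52 RPKM in the control and 2.21, level1_lnc-211 with 0.951 and 1.52, AT1G18745 with 0.0820 and 0.655, and level1_lnc-312 with 0 and 0.281. AT2G43375 went from 3.27 to 15.4 RPKM in cold at 12 h, and AT4G13495, over 3 miRNA genes, from 1.98 to 12.1 in salt at 12 h.

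The annotated lncRNA AT1G15405 (chromosome 1, 5297875 to 5298166, minus strand), classed as a small RNA precursor, had the most reads in each of the 9 libraries. It had 712 RPKM in the control (693 to 731), 364 in salt at 3 h, 1.96-fold lower (1.87 to 2.04), and 946 in cold at 12 h, 1.33-fold higher (1.28 to 1.38). Rescaled, it was lower in every stress library but heat at 3 h (log2 0.04), from -0.12 in drought at 3 h and -0.17 in cold at 12 h to -1.10 in salt at 3 h and -1.27 in salt at 12 h.

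Compared with the 3 h library of the same stress in place of the control, 48 lncRNAs were higher and 14 lower in cold at 12 h (77.4% higher), 58 and 5 in heat (92.1%), 69 and 13 in salt (84.1%) and 88 and 12 in drought (88%). Rescaled, the shares were 76.6%, 89.1%, 68.1% and 72.5%; the rule favours increases, so 50% is not what balanced changes would give. With each library in turn as the reference for the 8 others, the median share of higher lncRNAs was 72.3% for the control, 70.3%, 80.7%, 58.3% and 59.2% for the 3 h libraries of cold, heat, salt and drought, and 26.4%, 32.5%, 18.3% and 13.6% for those of 12 h. Rescaled, these were 63.8%, then 70.5%, 66.3%, 50.4% and 66.2%, then 34.2%, 34.1%, 30.1% and 32.0%.

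The authors' class of a conserved structure is YES for 995 of 995 predicted transcripts, of which 122 have an SCI above 0.5, while it is YES for 124 of 469 annotated ones, of which 122 do. A match to stress-related structures is given for 61 annotated (13.0%), 86 predicted (8.64%) and 186 of 4396 level 3 loci (4.23%). Binding of PIF4, a transcription factor of the light and temperature response, is given for 45 annotated and 60 predicted transcripts, and that of PIF5 for 24 and 30. All 58 predicted Poly(A)- transcripts of the authors' list are called level 2 there, while 22 are level 1 in the full matrix.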
